A study of Meriones unguiculatus and Mus musculus with 2 samples.

How the data were processed

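Gene expression was measured by RNA sequencing in 1 library of gerbil and 1 library of ICR mouse wounded skin, 3 days after wounding; the tissue label says dermis. Groups were taken from the sample labels. The deposited table gave FPKM for both species, per the file headers. The header places the gerbil values under expression measured after assembly and gives each an expectation value, so a gerbil FPKM was read here as that of an assembled sequence matched to a mouse gene, which the header does not spell out. The search program, the assembler and whether nucleotide or protein sequences were compared are not given in the sources used here. A weak match means only a larger expectation value. The submitters' processing notes name CASAVA, STAR 2.4.0b, RSEM 1.2.19, Cufflinks 2.2.1 and the mouse build GRCm38.p2, without saying which step or library each served. Coordinates are those of the table, on GRCm38, and span whole genes.

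The table listed 41214 genes, of which 221 had no value in either library, including 37 mitochondrial genes and 182 on chromosome 8. The 21056 gerbil values comprised 4561 distinct numbers, and up to 365 genes shared a value above 0. Values have 2 decimals, so low values also coincide by rounding: only 27 of 11727 gerbil values under 10 FPKM were listed for a single gene, against 1719 of 9329 at 10 or more. The subset of genes whose gerbil value was listed for no other gene therefore favours genes that are high in gerbil. A gerbil value of 0 was listed for 563 genes. ICR values summed to 619514 and distinct gerbil values to 413719. Neither sum is a depth, and depth is unknown.

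Differences were computed as log2(FPKM + 1) in gerbil minus log2(FPKM + 1) in ICR. This understates differences of low genes, and folds in the text are on that scale. A gene was measured if it had both values and at least 1 FPKM in at least 1 library, which left 20089 of 21023 symbols. Where a symbol had several entries, the entry with the highest mean stood for it. With 1 library per group no test was run, and a 4-fold size rule was used. Fixed gene lists (33) covered wound cell types and pathways, and the 30 with at least 5 measured members were given a median. Each median was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list in the outer 5% of random lists, split evenly between the ends, was called displaced, which applied to 4 lists. By chance 1.5 would be, if members were independent draws from a comparable pool. Members of a list can share a gerbil value and the pool holds pseudogenes, so 4 against 1.5 is not a test. The exact 95% interval of a median comes from its ordered members and describes spread over genes, not animals. The mitochondrially encoded list had no values.

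Genes were named by a rule set before the data were examined: the 12 highest and 12 lowest differences among symbols at 10 FPKM or more in both libraries, the 2 most abundant members and the 1 most different member of each list, the 5 highest genes listed at 0 in the other library, and Tgfb1, Tgfb2, Tgfb3, Col1a1, Col3a1, Acta2, Il1b, Il6, Tnf and Il10. Other list members, genes without a gerbil match, and genes with no related mouse sequence were named after their values were seen. Many genes that the rule takes in are not described, and which of them to describe was decided after their values were seen. Some genes that the rule or the lists take in are not reported here.

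Mouse coding genes with no related mouse sequence were found from the GENCODE M21 annotation, independently of expression. The longest coding sequence of each gene was searched with blastn 2.17.0 against all others and against pseudogene transcripts, and a gene with a hit at an expectation value of 1e-05 or less over at least 100 bases was set aside. Of the table's genes, 40340 were found in that annotation. This subset, protein-coding genes, gerbil values listed for no other gene, matches with an expectation value of 0, and random lists matched on match strength were added after the data were examined. Set beforehand were other pseudocounts, floors, scalings and size rules, and summed entries. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

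The procedure was tested on simulated data for the gerbil and ICR comparison with 12051 genes, 200 of them changed 16-fold. All 51 changed genes with an ICR value of at least 20 passed 4-fold in the right direction (100%), and 1 unchanged gene passed. Simulated noise had an SD of 0.5 on the log2 scale, against 1.505 across real genes with no related mouse sequence. Shared gerbil values, values of 0 and wrong matches were not simulated, so these counts do not give the error rate in the real libraries. A list displaced 2-fold reached percentile 100, and 1 of 25 unmoved lists was called.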

Results

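RNA sequencing profiled wounded skin of a Mongolian gerbil (Meriones unguiculatus) and of an ICR mouse, an outbred laboratory stock, 3 days after wounding. The labels name the samples skin and their tissue dermis; Krt1, an epidermal keratin, was at 2471 FPKM in ICR and 2469 in gerbil. Each species had 1 library, so the differences below have no replicate check, no test and no p-value, and they describe these 2 libraries only. The deposited table listed 41214 mouse genes. It held 40993 ICR values and 21056 gerbil values, both in FPKM, fragments scaled to transcript length and to the library's total. The gerbil values were read here as those of assembled gerbil sequences matched to mouse genes, so related mouse genes could carry the same gerbil value, and 19937 genes with an ICR value had no gerbil match. Sequencing depth was unknown because no counts were used, and no interval that needs depth is given.

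For 5518 mouse coding genes no related coding sequence or pseudogene was found in the mouse annotation, though some still shared gerbil values with other genes. Their median log2 difference (gerbil minus ICR, on FPKM + 1) was 0.17 (SD 1.505 across genes). Of these genes, 1603 reached 10 FPKM in both libraries, a floor that itself removes large differences; their median was 0.00 (SD 0.93), and 76.7% lay within 2-fold. Across the 5518 genes, 323 were at least 4-fold higher in gerbil and 403 at least 4-fold higher in ICR. This subset was chosen after the data were examined. In the planned count over all 20089 measured gene symbols, 5199 were at least 4-fold higher in gerbil and 1116 at least 4-fold higher in ICR. Thus 82.3% of the genes past 4-fold lay on the gerbil side (exact 95% interval 81.4 to 83.3). Such intervals cover counting error only and are too narrow where genes that share 1 gerbil value are counted as independent. Much of the excess on the gerbil side lay in pseudogenes: 2825 of 3435 measured pseudogenes passed 4-fold on the gerbil side, with a median log2 difference of 5.39. Protein-coding genes alone gave 1374 higher in gerbil and 1043 higher in ICR, or 56.8% on the gerbil side. With 1 FPKM required in both libraries, which removes genes near 0 in ICR, 801 were higher in gerbil and 851 in ICR, or 48.5% on the gerbil side (interval 46.1 to 50.9). The split was 73.5% after a trimmed mean of log ratios scaling, which lowered gerbil by 0.54 on the log2 scale. It was 45.4% after scaling to ribosomal protein and housekeeping genes, which lowered gerbil by 1.94, and under that scaling a gene less than 3.84-fold higher in gerbil changed side. Across genes, which are not independent replicates, Pearson's r between the libraries was 0.20 over all measured symbols and 0.65 over coding genes with no related mouse sequence (Spearman's rho 0.24 and 0.64).

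**Figure D1:**
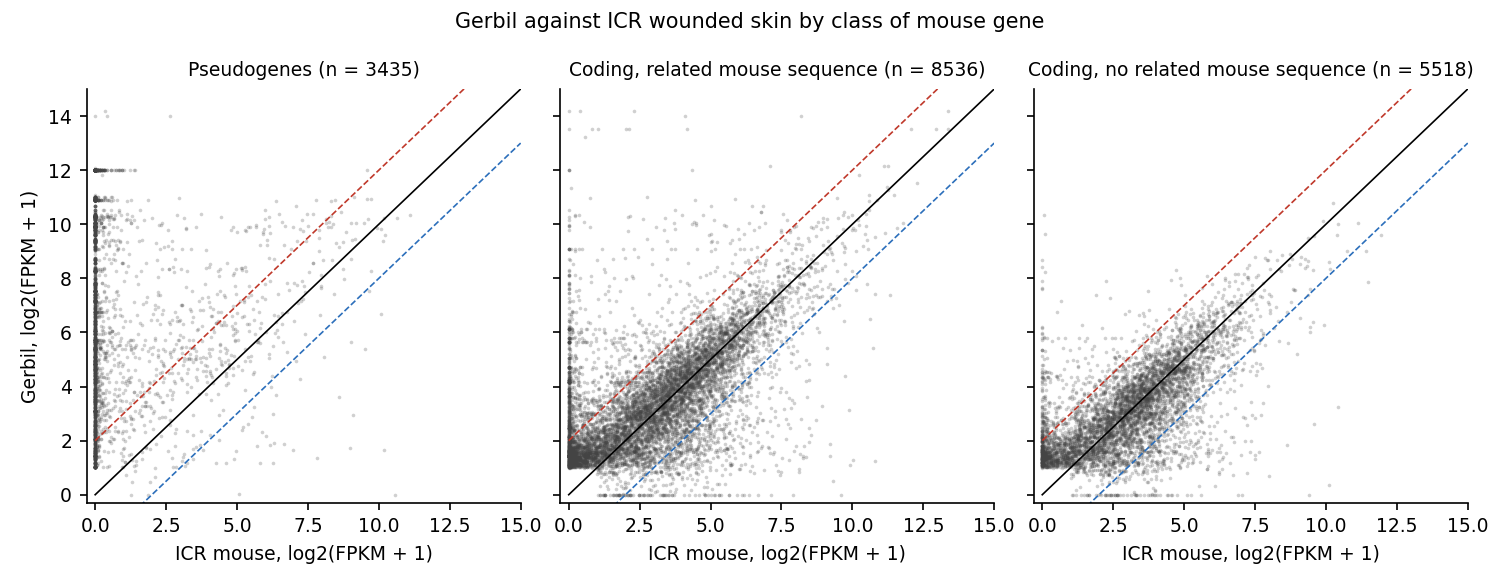
Gerbil against ICR expression, both as log2(FPKM + 1), with 1 point per measured gene, for pseudogenes (3435), coding genes with a related mouse sequence (8536) and coding genes with none (5518). The solid line marks equal values and the dashed lines 4-fold differences; 2825 pseudogenes lie above the upper dashed line, against 323 of the coding genes with no related sequence.

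Genes of the differentiated layers of the epidermis were lower in the gerbil wound. Of 16 measured members of this list, 12 were lower in gerbil and 4 higher, with 6 at least 4-fold lower, and the median log2 difference was -1.60 (exact 95% interval over members -2.38 to 0.33). Krtdap, a secreted protein of differentiating keratinocytes (chromosome 7, 30787896 to 30791097, GRCm38), was at 3923 FPKM in ICR and 776 in gerbil. Sbsn, suprabasin, was at 2700 and 515 FPKM, and the cornified envelope protein Lor at 692 and 194. Flg, the precursor of the filament-aggregating protein of the cornified layer, was at 174 FPKM in ICR and 32.5 in gerbil. The list was not lower throughout: Krt1, the type II keratin of the suprabasal layers, was level at 2471 and 2469 FPKM, and the envelope precursor Ivl was higher in gerbil, at 86.4 and 260, by less than the 3.84-fold of the ribosomal and housekeeping scaling. Krt2, at 0.048 and 2610 FPKM, rested on a weak match (expectation value 2e-33). The median lay at percentile 0 of 10000 random lists matched on mean expression. It was -1.49 at percentile 0.13 for the 10 members whose gerbil value was listed for no other gene, and -0.91 at percentile 0.80 (interval -2.61 to 1.35) for the 8 members matched with an expectation value of 0.

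The basal and wound-edge keratinocyte lists lay within the central 95% of random lists over all measured genes. The 15 basal keratinocyte genes had a median log2 difference of 0.83 (interval -0.40 to 1.84, percentile 87), and -1.09 under the ribosomal and housekeeping scaling. Sfn, the 14-3-3 protein of stratified epithelia, was at 2813 FPKM in ICR and 2138 in gerbil, and the hemidesmosome collagen Col17a1 at 233 and 432. The keratins of this group cannot be compared gene by gene: Krt14 was listed at 0 in ICR and at 18470 FPKM in gerbil, the gerbil value it shared with Krt16, which was at 10653 in ICR. Krt5, at 4284 and 11792 FPKM, shared its gerbil value with Krt6a and Krt6b. The 12 measured wound-edge keratinocyte genes, induced at a healing margin, had a median of -0.41 (percentile 2.72). Among them Krt17 was at 4984 FPKM in ICR and 2909 in gerbil, while the growth factor genes Areg (28.6 and 62.2) and Hbegf (38.9 and 65.8) were higher in gerbil, by less than the ribosomal and housekeeping scaling would remove. Gjb2, a gap junction gene of migrating keratinocytes, was at 770 FPKM in ICR and listed at 0 in gerbil.

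Interferon response genes were also lower in gerbil. Of 13 measured members 12 were lower and 4 at least 4-fold lower, with a median log2 difference of -1.44 (interval -2.37 to -0.16, percentile 0.01). Isg15, the ubiquitin-like protein induced by type I interferon (chromosome 4, 156199424 to 156200818), was at 164 FPKM in ICR and 4.94 in gerbil. Irf7, a transcription factor that drives interferon production, was at 54.8 and 2.65, and Bst2, the membrane protein tetherin, at 98.8 and 35.9. Gbp2 was the member higher in gerbil, at 13.3 and 18.6 FPKM, and it was lower after the trimmed mean and the ribosomal and housekeeping scalings.

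Inflammatory cytokines and chemokines moved in both directions. Of 18 measured members 10 were higher and 8 lower in gerbil, and the median of 0.36 lay at percentile 46.7. Il6 (chromosome 5, 30013161 to 30019968) was at 1.11 FPKM in ICR and 30.2 in gerbil, a 14.8-fold difference on the FPKM + 1 scale. The monocyte chemoattractant Ccl2 was 7.23-fold higher in gerbil (28.6 and 213 FPKM), and Osm, oncostatin M, 4.85-fold higher (54.5 and 268). The prostaglandin synthase Ptgs2 was at 102 FPKM in ICR and 403 in gerbil. Il1b, the most abundant member of the list in ICR, was at 1222 and 1781 FPKM, and the neutrophil chemoattractant Cxcl2 at 1209 and 3646. In the other direction Ccl4 was 9.64-fold higher in ICR (700 and 71.8 FPKM), and Tnf was at 56.0 in ICR and 1.92 in gerbil. The interleukin-1 antagonist Il1rn was at 254 and 611 FPKM, and the anti-inflammatory cytokine Il10 was low in both, at 0.76 and 3.28.

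Monocyte and inflammatory macrophage genes had a median of -0.76 over 9 measured members (interval -3.17 to 0.64), 4 higher and 5 lower in gerbil, at percentile 1.77, and this displacement was lost among protein-coding genes alone (percentile 3.96), with 1 FPKM required in both libraries (29.8) and with a pseudocount of 0.1 (2.83). Cd14, the lipopolysaccharide co-receptor, was at 1332 FPKM in ICR and 784 in gerbil, and the monocyte chemokine receptor Ccr2 at 43.2 and 3.34, whereas Csf1r, the receptor of macrophage colony-stimulating factor, was at 77.6 and 111. The integrin chain Itgam (71.5 and 797 FPKM), whose gerbil value was shared with other genes, differed most, at 3.46 against -3.35 for Ccr2. With a pseudocount of 0.1 or the trimmed mean scaling, the largest difference in the list lay on the ICR side. Alternatively activated macrophage genes had a median of -0.01 (10 members, mean 0.23). Within that list the scavenger receptor Cd163 was 12.4-fold higher in gerbil (10.3 and 140 FPKM), and Arg1, arginase 1, was at 325 in ICR and 30.5 in gerbil on a weak match (2e-19). The 9 measured neutrophil genes had a median of -0.06 (interval -4.18 to 2.22). At least 4-fold differences went both ways, 3 higher and 2 lower in gerbil. The trimmed mean scaling left 0 higher and 3 lower, and the ribosomal and housekeeping scaling 0 and 4. Fpr1, a formyl peptide receptor, was at 29.5 and 141 FPKM, a gerbil value shared with Fpr2. Lcn2, lipocalin 2, was at 132 and 6.38, and Clec4d at 247 and 2.07 on a weak match (8e-09). The neutrophil chemokine receptor Cxcr2 was close to level, at 67.0 and 64.0 FPKM.

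Structural matrix genes had a median of -0.09 over 21 measured members (percentile 7.13), 10 higher and 11 lower in gerbil. Members whose gerbil value was listed for no other gene had a median of 0.73 (12 members, percentile 98.8), a subset that favours high gerbil values. Members with no related mouse sequence had a median of 0.95 (6 members, interval -4.37 to 2.74, percentile 99.0). Both subsets were chosen after the data were examined, and both medians are smaller than the 1.94 by which the ribosomal and housekeeping scaling lowers gerbil. The matricellular protein Tnc, tenascin C, was at 56.4 FPKM in ICR and 294 in gerbil, and fibronectin Fn1 at 111 and 286. The chains of collagen VI differed in direction: Col6a1 was at 48.2 and 201 FPKM and Col6a3 at 50.7 and 74.0. Col6a2 was at 46.3 and 1.29, a gerbil value shared with other genes, as low values often are by rounding alone. Those of type I collagen also differed in direction: Col1a1 was at 567 and 203 FPKM and Col1a2 at 502 and 1079. Their matches differed too, with expectation values of 3e-138 for Col1a1 and 0 for Col1a2. The small proteoglycan Dcn, decorin, was lower in gerbil, at 482 and 162. Col3a1 (1794 and 1.37 FPKM) and Sparc (965 and 1.15) had weak matches, with expectation values of 9e-14 and 7e-28. Collagen processing genes had a median of 0.32 over 18 members; the collagen chaperone Serpinh1 was at 313 and 409 FPKM.

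Transforming growth factor beta pathway genes had a median of 0.54 over 19 members (percentile 57), and -1.09 under the ribosomal and housekeeping scaling. Tgfb1, the main isoform of platelets and leukocytes, was at 41.4 FPKM in ICR and 29.3 in gerbil, Tgfb2 at 1.03 and 3.35, and Tgfb3 at 1.57 and 15.6, or 6.49-fold higher in gerbil. The matricellular genes Thbs1 (180 and 534 FPKM) and Tgfbi (209 and 631) were each about 3-fold higher, and the receptor Tgfbr2 was lower, at 46.6 and 10.02. The 14 contractile myofibroblast genes had a median of 0.82 (percentile 55.5), with 11 higher and 3 lower in gerbil, and 2 past 4-fold on each side. Acta2, smooth muscle actin, was at 42.5 FPKM in ICR and 169 in gerbil, but Actb, cytoplasmic actin, carried the same gerbil value and was at 1789 in ICR. Tagln, transgelin, whose gerbil value was its own, was at 15.9 and 74.1 FPKM. The actin Actg2 was at 1.95 and 419 FPKM, a shared gerbil value. The tropomyosin Tpm2 was at 203 and 5.93 and the caldesmon Cald1 at 41.3 and 2.80. Their gerbil values were also shared, as values that low often are by rounding alone.

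**Figure D2:**
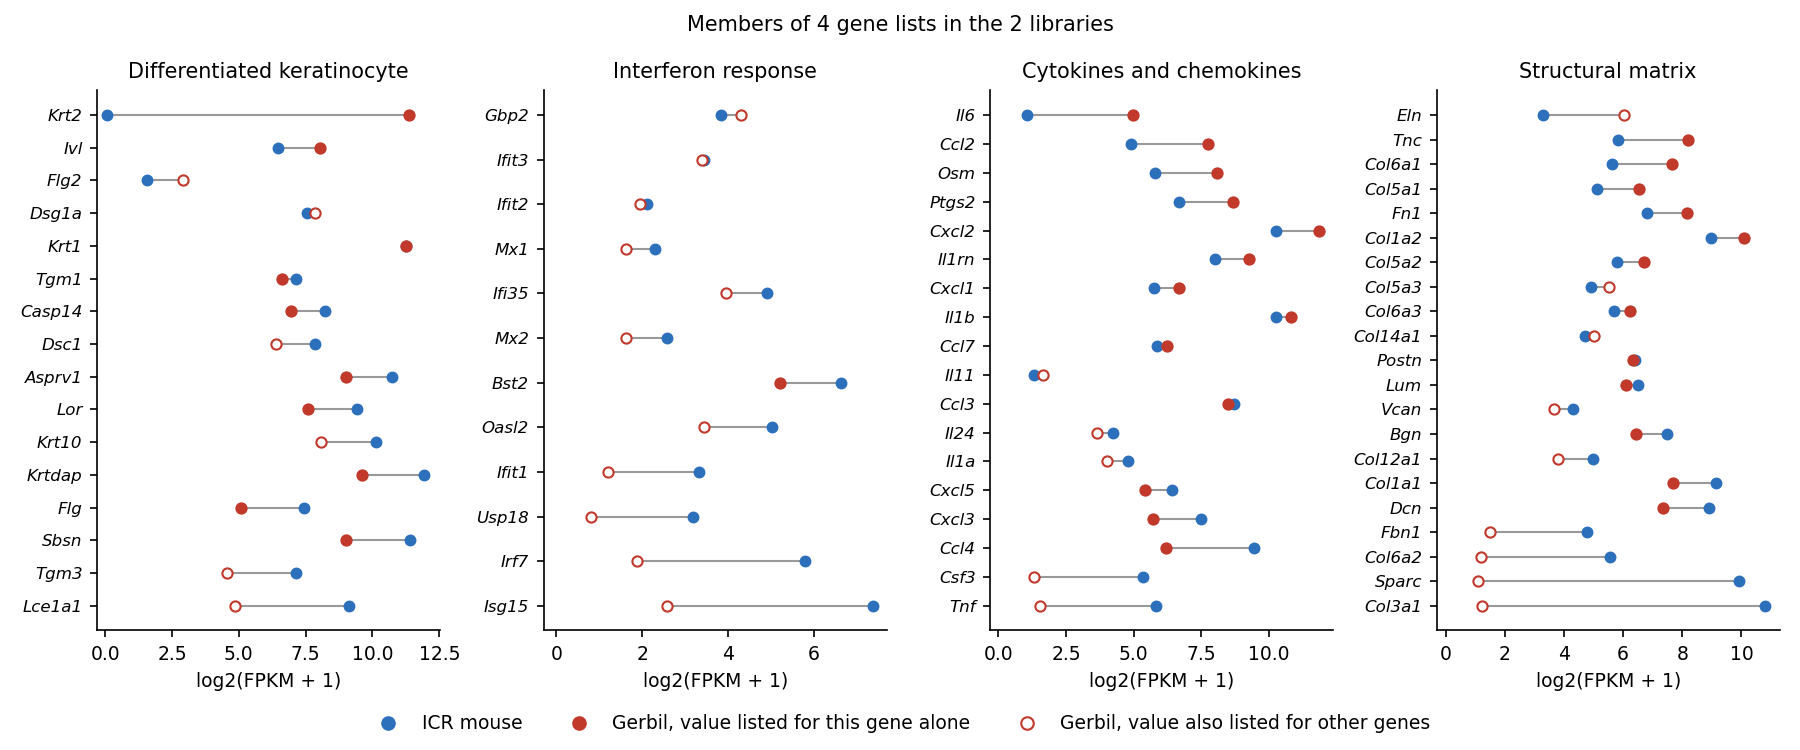
Expression of measured members of 4 gene lists as log2(FPKM + 1) in ICR (blue) and gerbil (red). Open symbols mark gerbil values also listed for other genes, which low values often are by rounding alone. Differentiated keratinocyte genes (12 of 16 measured members) and interferon response genes (12 of 13, not all drawn) were mostly lower in gerbil, while cytokines and structural matrix genes lay on both sides.

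**Figure D3:**
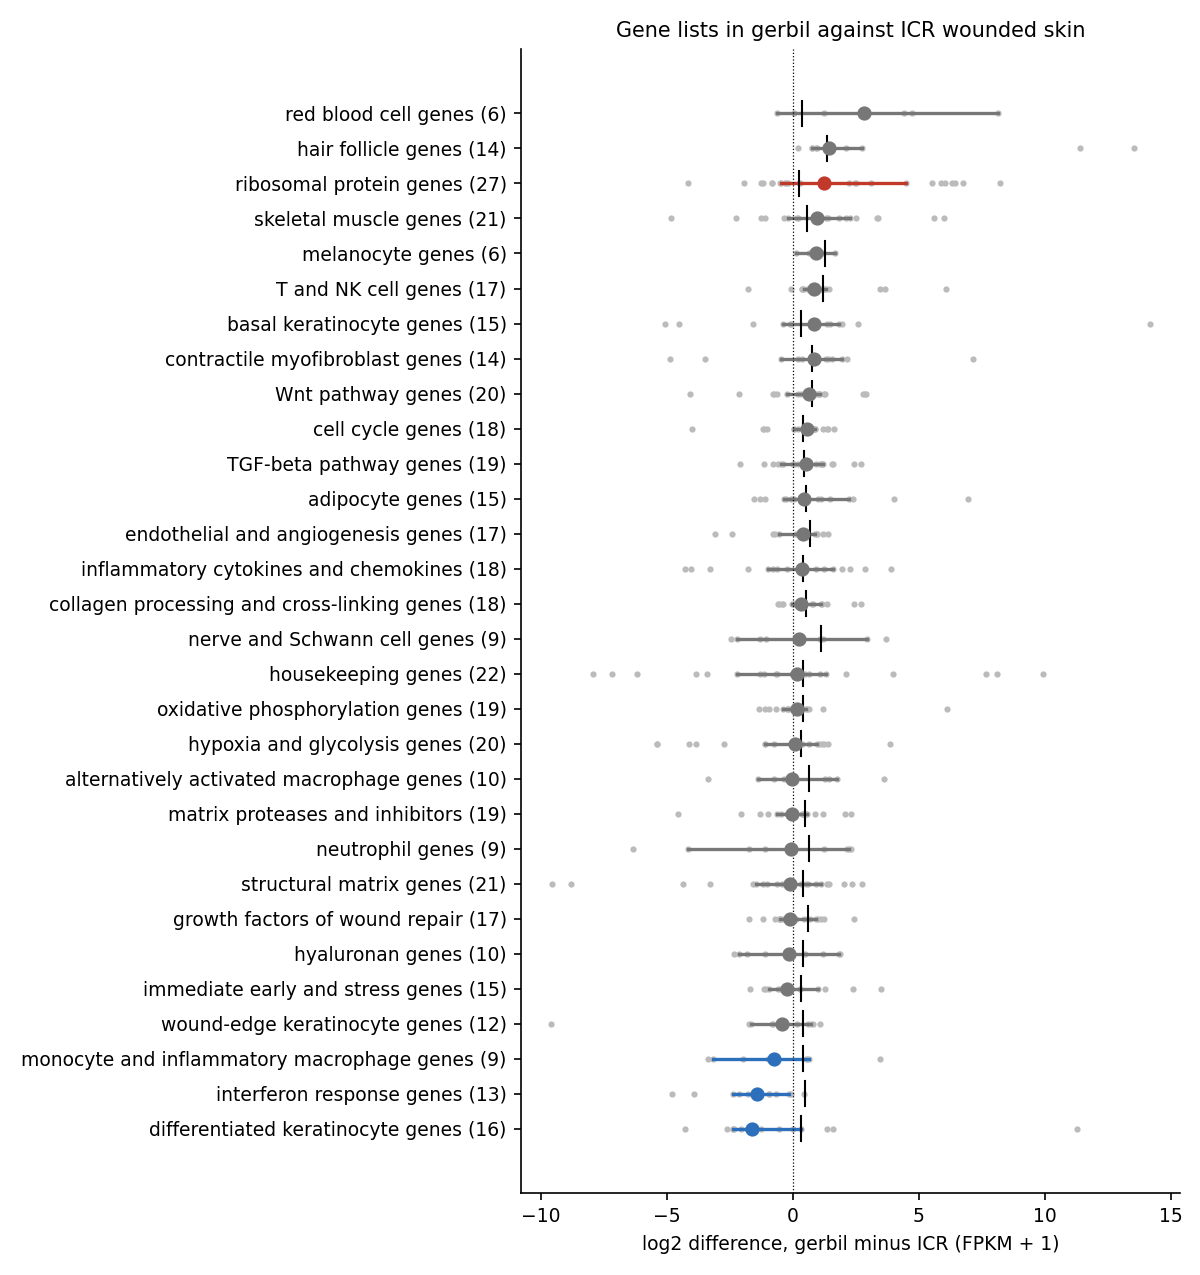
Median log2 difference (gerbil minus ICR, FPKM + 1) of 30 gene lists, with the exact 95% interval over members as a line, members as grey points, the number measured in parentheses, and the median of matched random lists as a black tick. Lists outside the central 95% of random lists are blue where low and red where high; differentiated keratinocyte genes, at -1.60, are lowest, and the red ribosomal protein list falls to -0.69 under the ribosomal and housekeeping scaling.

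Among genes at 10 FPKM or more in both libraries, those with the largest ratios on the gerbil side were ribosomal protein, ubiquitin and Gapdh genes and related pseudogenes, whose gerbil values were shared with other genes and are uncertain. They included Gapdh, Rps18, Rps3a3, Rps2, Rpl3, Rps15a-ps3, Rpl11, Rpl19, Ubb, Rps16 and Rps29; Gapdh, for example, was at 19.5 FPKM in ICR and 4158 in gerbil. Ribosomal protein genes had a median of 1.24 over 27 members (interval -0.48 to 4.48, percentile 99.3), and -0.69 under the ribosomal and housekeeping scaling, which these genes help to set. Their percentile was 99.2 under that scaling, but 60.8 with a pseudocount of 5, where the list was not displaced. On the ICR side the largest ratios were in Ece1, Ftl1, Eno1b, Txndc17, Lce1a1, H3f3a, Ptpn18, Plin2, Pkm, Fth1, Mrpl52 and Ifitm1. Ece1, endothelin-converting enzyme, was at 860 FPKM in ICR and 20.1 in gerbil, a value listed for no other gene, and Mrpl52, which has no related mouse sequence, was at 249 and 15.2. The ferritin chains Ftl1 (1710 and 41.4) and Fth1 (2595 and 165) had weak matches of 3e-25 and 4e-25. Those of Eno1b (8e-20) and Txndc17 (4e-20) were weaker still. H3f3a was matched at 2e-43, Lce1a1 at 2e-47, Plin2 at 2e-60 and Mrpl52 at 6e-70. Of these largest ICR-side ratios, only Ece1 and Ptpn18 had an expectation value of 0. Gm9843, Capzb, Rab7 and Nhp2 were listed at 0 in gerbil, at 1521, 683, 242 and 139 FPKM in ICR. Of these, Gm9843 (1e-23), Rab7 (1e-33) and Nhp2 (3e-12) had weak matches. Gm12328, Krt73, Krt74 and Gm21045 were listed at 0 in ICR. Capzb and Rab7 are used by every cell, so a value of 0 is not read as absence.

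Lists of other cell types were not displaced over all measured genes. Skeletal muscle genes had a median of 0.97 over 21 members, at percentile 80.0, and at percentile 99.4 among protein-coding genes alone; Mylpf, a fast muscle myosin light chain, was at 70.4 FPKM in ICR and 177 in gerbil. Red blood cell genes had a median of 2.82 over 6 members (percentile 96.9), where the alpha globin Hba-a1 was at 272 and 279 FPKM and its copy Hba-a2 was listed at 0 in ICR. Medians were 0.84 for T and NK cell genes, 1.45 for hair follicle genes, 0.44 for adipocyte genes, 0.41 for endothelial genes, 0.23 for nerve and Schwann cell genes and 0.93 for melanocyte genes, none of them outside the central 95% of random lists. Against protein-coding genes alone the hair follicle (percentile 98.9), red blood cell (99.9) and basal keratinocyte lists (98.5) lay above it. The nerve and Schwann cell list lay below the central 95% under the trimmed mean scaling (median -1.47), the ribosomal and housekeeping scaling (-2.66) and a floor of 5 FPKM (-1.18). The B cell and mast cell lists had 4 and 3 measured members and no median, and 7 mast cell genes had no gerbil match. In the mast cell list Hdc, histidine decarboxylase, was at 278 FPKM in ICR and 0.79 in gerbil. Tpsab1 went the other way, at 2.39 and 5.56. Many abundant ICR genes had no gerbil value, among them the keratinocyte lectin Lgals7 (13701 FPKM), the alarmins S100a9 (4550) and S100a8 (3242), and Lyz2 (1717). The neutrophil list therefore lacked S100a8 and S100a9, among 7 of its genes with no gerbil match. The monocyte list had 6 such genes, Lyz2 included, the wound-edge keratinocyte list 6 and the interferon list 5.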

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

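Settings that restrict the genes, by coding class, related sequence, sharing or match strength, and random lists matched on match strength were chosen after the data were examined. Differentiated keratinocyte and interferon response genes stayed below percentile 2.5 and negative under every setting that left at least 5 members. No paired analysis was possible because each species had 1 library, and no library could be left out. Length-free values from counts and random lists matched on length were not run, since no counts or lengths were used. The cause of the shifts below was not tested, except that restricted gene sets hold fewer genes by construction. A list median is called moved where it left its own interval over members.

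Genes at least 4-fold higher in gerbil numbered 8258 with a pseudocount of 0.1, 3322 with 5, 801 with 1 FPKM required in both libraries (851 higher in ICR), 3206 under ribosomal protein and housekeeping gene scaling, 1374 among protein-coding genes, 323 with no related mouse sequence, 130 with an unshared gerbil value and 2152 with an expectation value of 0. Genes higher in ICR numbered 557 with a pseudocount of 5, 3857 under ribosomal and housekeeping scaling, and 403, 36 and 684 in the last 3 subsets. A 2-fold rule gave 9488 and 2591, and an 8-fold rule 3842 and 505. Pearson's r was 0.63 with 1 FPKM in both, 0.61 for protein-coding genes, 0.65 with no related sequence, 0.60 unshared, 0.24 at an expectation value of 0 and 0.12 with a pseudocount of 0.1.

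Under the ribosomal and housekeeping scaling, which lowers every gerbil value by 1.94 and is set partly by that list, the ribosomal protein median turned negative by construction, at -0.69, and stayed high among random lists (percentile 99.2). The same scaling moved the medians of alternatively activated macrophage (-2.07), cytokine (-1.45), interferon response (-2.91), T and NK cell (-0.58), structural matrix (-1.98), collagen processing (-1.58), myofibroblast (-1.18), TGF-beta pathway (-1.09), protease (-1.67), endothelial (-0.84), basal (-1.09), differentiated (-3.51) and wound-edge keratinocyte (-2.29), hair follicle (0.74), Wnt (-0.998), growth factor (-1.87), skeletal muscle (-0.60), adipocyte (-1.34), nerve (-2.66), cell cycle (-1.30), hypoxia (-1.68), oxidative phosphorylation (-1.71) and immediate early genes (-2.03). Medians shifted as far but stayed within wider intervals for monocyte (-2.70), neutrophil (-2.08), hyaluronan (-1.95), red blood cell (0.88) and housekeeping genes (-1.73). The trimmed mean scaling gave -0.22 for collagen processing, -0.68 for growth factors, 0.030 for cell cycle and -0.37 for oxidative phosphorylation. A pseudocount of 0.1 gave 1.65 for T and NK cell, 2.99 for hair follicle and 2.46 for melanocyte genes, and a pseudocount of 5 gave 0.30 and 0.46 for the first 2. Unshared cell cycle genes had a median of 1.195. Upper quartile scaling, which lowers gerbil by only 0.07, and summed entries left every list median within its interval. Other lists left or entered the outer 5% only in some settings. With a pseudocount of 5 the ribosomal list moved inside (percentile 60.8), and structural matrix (1.91), wound-edge keratinocyte (0.75) and immediate early genes (1.93) moved outside. The nerve list was low under the trimmed mean scaling (0.65), the ribosomal and housekeeping scaling (0.25) and a floor of 5 FPKM (1.90). Skeletal muscle was high with 1 FPKM in both (99.7), and unshared cytokine (99.7) and hypoxia genes (98.3) were high in a subset that favours high gerbil values.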

Other observations

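The test of each explanation for the keratinocyte and interferon lists, the ribosomal protein test and the test of scaling were chosen after the values were seen. The prediction for carried-over values was written before its test was run, but the subset it used was added after the data were examined. Scaling was first tested by upper quartile scaling (81.1% on the gerbil side), which moved values by only 1.05-fold and was dropped. For the keratinocyte list, match strength and sharing were first tested on the intervals of medians, which left both undecided (-0.91, interval -2.61 to 1.35, for 8 members with an expectation value of 0, and -1.49, interval -2.38 to 1.58, for 10 unshared members); the percentile tests below replaced them.

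Genes with no related mouse sequence, named after their values were seen, also differed. At 10 FPKM or more in both libraries, the largest gerbil-side ratios were in Tlcd1 (12.1 FPKM in ICR and 182 in gerbil) and Slc35b2 (25.2 and 313). Their gerbil values were listed for 48 and 11 genes. Also on the gerbil side were Igfbp3, a carrier of insulin-like growth factors (22.1 FPKM in ICR and 243 in gerbil), Sod2, the mitochondrial superoxide dismutase (28.2 and 259), and Ptgis, prostacyclin synthase (10.9 and 106). Clec5a, a myeloid lectin, was at 10.9 and 79.3 FPKM. On the ICR side, with no theme tested, were Mrpl52 (249 and 15.2), Rptn, repetin (503 and 35.6), Cnfn, cornifelin (983 and 77.3), Pkp3, a desmosome plakophilin (693 and 63.0), and the protease inhibitor Spink5 (323 and 49.97). Apoe, apolipoprotein E, was at 2867 and 234 FPKM, and the alarmin cytokine Il33 at 400 and 48.4.

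Lists not described above lay within the central 95% of random lists. Medians were 0.56 for cell cycle genes (18 members), 0.09 for hypoxia and glycolysis (20 members, mean -0.66), 0.16 for oxidative phosphorylation, 0.66 for Wnt pathway genes, -0.03 for matrix proteases and inhibitors, -0.14 for hyaluronan genes, -0.12 for growth factors (mean 0.12), 0.16 for housekeeping genes and -0.22 for immediate early genes (mean 0.14). Timp1 was level at 169 and 166 FPKM, Ldha at 1848 and 1905, and Fosb was at 6.03 in ICR and 79.2 in gerbil.

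The excess of genes past 4-fold on the gerbil side may come from gerbil values carried over to several related mouse genes. Among genes with no related sequence, 44.5% of the genes past 4-fold were higher in gerbil. That subset also leaves out genes with pseudogene copies, so the 44.5% cannot tell carried-over values from low ICR values of such genes. Some genes with no related sequence still shared a gerbil value with other genes. Genes with an unshared gerbil value kept 78.3%, in a subset that favours high gerbil values. Low ICR values of genes with pseudogene copies may add to it: across 76 ribosomal protein genes, ICR FPKM fell with the number of related pseudogenes (Spearman's rho -0.48, and -0.08 for gerbil FPKM; genes are not independent replicates). A factor common to all genes, such as scaling, would also shift genes with no related sequence. There the share was 44.5% (exact interval 40.8 to 48.2), which scaling as the whole cause would not give. This is the same value as for carried-over values. It was known when the scaling prediction was written, so it is not a separate test. Upper quartile scaling changed values too little to bear on this, the ribosomal and housekeeping scaling gave 45.4% but rests on genes with pseudogene copies, and no biological explanation was tested.

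Whether weak matches account for the lower level of differentiated keratinocyte genes in gerbil was not settled. The list lay at percentile 0 of random lists matched on match strength, but these drew on pseudogenes too. Their median was 0.50, against 0.35 without that matching, which favours a low percentile. The 8 members with an expectation value of 0 had a median of -0.91 (percentile 0.80, interval -2.61 to 1.35). Shared values do not explain the lower level of the 10 members with unshared values, whose median was -1.49 (percentile 0.13, 8 of them lower in gerbil). Their interval of -2.38 to 1.58 had left the first test undecided. The percentile test replaced it after the values were seen, so the question is not closed for the whole list. Less epidermis in the gerbil sample cannot be told apart from lower expression: the 7 basal keratinocyte genes with unshared values had a median of -0.070, with an interval of -1.58 to 1.84. All 15 basal genes had a median of 0.83, but shared keratin values enter it. Species, sampling and the stage of repair are confounded in these libraries, so no biological explanation could be tested.

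Weak matches were likewise not settled as an explanation for the lower level of interferon response genes in gerbil. The list lay at percentile 0 of random lists matched on match strength, whose median was 0.67, against 0.49 without that matching. The 8 members with an expectation value of 0 had a median of -1.27 (percentile 0.32, interval -3.93 to 0.45), 7 of them lower in gerbil. An effect of shared values cannot be told apart from lower expression, because the 4 members with no related mouse sequence are too few for an exact 95% interval; their median was -1.90, and they ranged from -3.93 to -0.95. A difference between the species stays open and untested.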
